A study of Homo sapiens with 12 samples.

How the data were processed

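Polyadenylated RNA was sequenced from 12 samples of the MDA-MB-231b line, 3 in each of 4 groups formed by 2 genotypes and 2 treatments. MDA-MB-231 is an established human triple-negative breast cancer line. The b derivative is bone-tropic and was made, per the series design text, by passing the cells through the bone marrow of athymic nude mice. The text describes lentiviral CRISPR-Cas9 with a guide RNA against GLI2 or a non-targeted guide, and the labels call the genotypes GLI2 KO and WT. Cells received 50 nM paclitaxel, a microtubule-stabilising taxane, or its solvent DMSO for 2 days. Groups were taken from the sample titles. The titles give no replicate number, so replicates were numbered within a group in accession order and were never paired. By library number, each odd sample and the next shared a genotype and differed in treatment. Whether they form pairs is not given in the sources used here. No paired fit was run, so any spread shared within such pairs was not taken out. Nothing in the labels says that the replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

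Per the labels, RNA was extracted with QIAzol and cDNA was made with qScript cDNA supermix. The submitters' processing notes name Trim Galore 0.6.7, STAR, DESeq2 1.36.0 and the hg38 build, with no roles. The counting tool, the gene annotation and the use of strand are not given in the sources used here. The deposited table of counts holds whole-number, unnormalised counts for 25049 genes, and its lowest row total is 20. The deposited table of normalized signal holds those counts divided by 1 size factor per sample, with a largest relative deviation of 5.33e-15 from such a factor, and it therefore adds no information to the counts. The number of columns not used was 0, and 0 rows lacked a gene name or identifier. Totals ran from 83230948 to 109018776 counts per sample. At these depths a level of 3 counts, used as the floor, equals 0.0275 to 0.0360 CPM (counts scaled to library size). Intervals and floors cover counting error only.

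Gene names were matched to GENCODE 29 on GRCh38, which may not be the annotation behind the counts. Of the 25049 genes, 23402 (93.4%) matched and 5586 carried only an Ensembl identifier. Coordinates and overlaps come from that annotation. Genes that overlap another gene, including antisense genes, may share counts with it because the use of strand is not stated, and the share of exon bases in common is given for named genes where it exceeds 20%. Replication-dependent histone genes and other close copies may exchange counts in the same way, so single members of those families are uncertain.

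The main test was edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, robust) on the counts, with TMM factors and filterByExpr by group at its default minimum count of 10, which left 21974 genes (87.7%). All 12 samples entered a fit with a mean per group and 8 residual degrees of freedom. The 5 contrasts were paclitaxel against DMSO in WT and in GLI2 KO cells, GLI2 KO against WT in DMSO and in paclitaxel, and the difference of the paclitaxel effect between genotypes. P-values were adjusted by Benjamini-Hochberg within a contrast and genes passed below 0.05. Values after ± on the log2 scale are approximate standard errors, computed as the absolute log2 fold change over the square root of F. Levels are TMM-scaled CPM with the SD of 3 replicates. All p-values are two-sided. With 3 samples against 3, the smallest exact permutation p is 0.1. For genes with 3 counts or fewer in a whole group, a ratio of summed counts over summed library totals replaces the fitted fold. It has an exact binomial 95% interval, or is given as a bound against 3 counts over the group. These ratios and bounds use no TMM factors, unlike the fitted folds.

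The groups, contrasts, tests, alternatives, 41 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per group comparison, the 10 largest rises and 10 largest falls among passing genes with a mean of at least 5 CPM in either group, a named symbol and replicates that did not overlap. For the difference of effects it took the same numbers without the condition on replicates. GLI2 was added everywhere, as were up to 4 passing members per list with the largest change at any level. Other genes are named with the reason. Some members of the lists are not reported here by name. Lists of at least 5 tested members were tested with limma's camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the 40 such lists within a contrast. Camera compares a list with all other genes. Every call at the preset correlation was lost when the correlation was estimated per list, and both adjusted p-values are given. The last 4 lists held markers of other cells that a cultured line passed through mouse bone could contain. Alternatives were RLE and upper-quartile factors, library totals alone, no low-count filter, a minimum count of 50, DESeq2, limma-voom, only the groups compared, camera with an estimated correlation, fry, and leaving out each replicate in turn.

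The test was checked on simulated counts drawn from the real library sizes, with the WT DMSO means in every group. At each of 4 sizes 50 genes were changed, all with a mean of at least 50 counts and as many raised as lowered. Nearly all simulated genes were unchanged, unlike in the real response to paclitaxel. The check therefore does not bear on the TMM factors under a broad or uneven response. Recovery of more weakly counted genes was not checked. For paclitaxel in WT cells, over 19271 simulated genes, it recovered 36 of 50 genes changed 1.2-fold, 46 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, with 17 false calls. For the difference of effects, over 19286 genes, it recovered 18, 38, 44 and 50, with 12 false calls. In 20 simulated data sets a G2/M list raised 1.2-fold was called in 20, and a mean of 0.2 of 35 unchanged lists was called. Simulated genes were drawn independently, so this check does not bear on the choice of the inter-gene correlation. The common biological coefficient of variation was 3.90%. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for annotation and figures.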

Results

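RNA from 12 samples of bone-tropic MDA-MB-231b breast cancer cells was counted per gene, with 3 samples each of WT cells in DMSO, WT cells in paclitaxel, GLI2 KO cells in DMSO and GLI2 KO cells in paclitaxel. Totals lay between 83230948 and 109018776 counts. Genes with at least 1 count numbered 23712 to 24125 in the DMSO samples and 24923 to 24985 in the paclitaxel samples. Mitochondrially encoded genes took 3.99% to 4.69% of counts in DMSO and 4.83% to 5.33% in paclitaxel. The leading principal component held 61.3% of the variance and parted the treatments, and the next held 20.8% and parted the genotypes. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom from 2.90 to 17.9, so no pair was treated as the same library. GLI2 KO DMSO replicate 3 stood furthest from its group (13.7 and 17.9 against the others). GLI2 KO paclitaxel replicate 3 (11.7 and 7.17) and WT DMSO replicate 2 (11.4 and 8.44) also stood apart from their groups. The GLI2 KO replicates 3 in DMSO and in paclitaxel were libraries 11 and 12. Whether they were prepared together is not given in the sources used here.

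**Figure D1:**
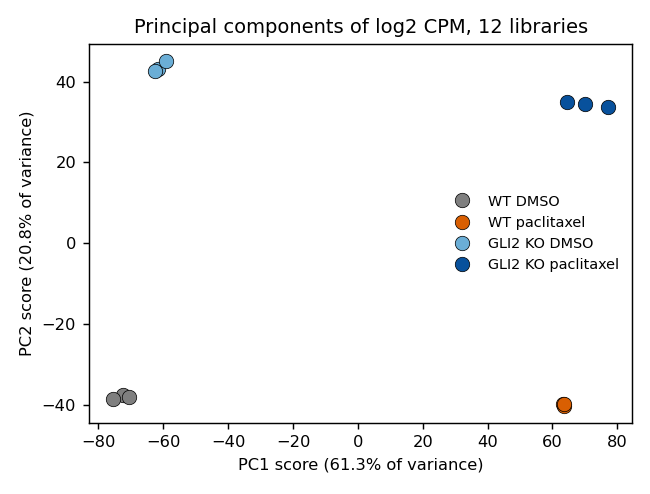
Scores of the 12 samples on the leading principal components of log2 CPM, with treatment and genotype marked per sample. The horizontal component (61.3% of variance) separates DMSO from paclitaxel and the vertical component (20.8%) separates WT from GLI2 KO.

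GLI2 encodes a zinc-finger transcription factor that acts at the end of Hedgehog signalling, and it was the gene targeted by the guide. The gene (ENSG00000074047) lies on chromosome 2 from 120735623 to 120992653, plus strand. Its transcript was present in the knockout cells. In DMSO the WT replicates held 10.4, 11.4 and 10.6 CPM and the GLI2 KO replicates 9.28, 8.23 and 10.1 CPM, a log2 fold change of -0.23 ± 0.08 (edgeR adjusted p = 0.0253), or a fall of 14.6%. In paclitaxel the WT replicates held 6.42, 5.65 and 4.97 CPM and the GLI2 KO replicates 3.97, 4.14 and 4.39 CPM, a log2 fold change of -0.44 ± 0.09 (adjusted p = 0.000243), or a fall of 26.4%. Paclitaxel lowered GLI2 in both genotypes, by 47.4% in WT cells (log2 fold change -0.93 ± 0.08, adjusted p = 7.45e-10) and by 54.6% in GLI2 KO cells (-1.14 ± 0.09, adjusted p = 3.94e-11). The 2 falls did not pass as different (difference -0.21 ± 0.12, adjusted p = 0.269). In each of the 4 comparisons the replicates did not overlap and the exact permutation p was 0.1, the smallest that 3 against 3 samples allow. The difference in DMSO lost its call without GLI2 KO replicate 1 (log2 fold change -0.23, adjusted p = 0.0577), GLI2 KO replicate 2 (-0.15, adjusted p = 0.183) or WT replicate 2 (-0.19, adjusted p = 0.110). GLI2 lies in a block of 50 neighbouring expressed genes on chromosome 2 that was lower in GLI2 KO cells as a whole (median -0.25 in DMSO and -0.26 in paclitaxel). The 50 expressed genes centred on GLI2 had medians closer to no change (-0.15 in DMSO and -0.12 in paclitaxel). A transcript level does not show whether the protein was lost, since an edited gene can still be transcribed, and the guide's target site is not given in the sources used here.

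**Figure D2:**
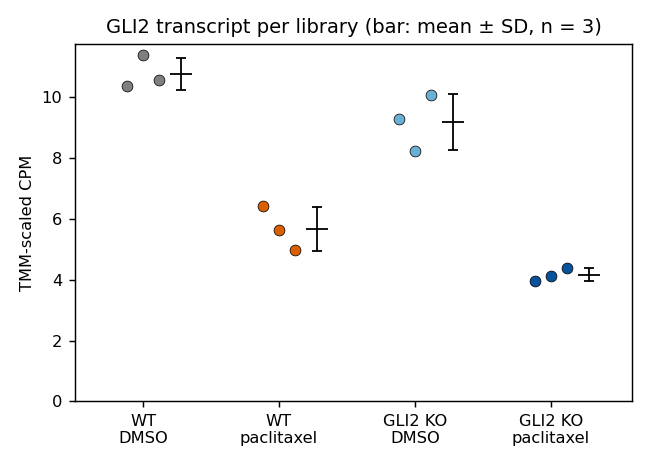
GLI2 transcript level in TMM-scaled CPM for each of the 12 samples, with the mean and SD per group (n = 3). Means were 10.8 CPM in WT DMSO, 9.20 in GLI2 KO DMSO, 5.68 in WT paclitaxel and 4.16 in GLI2 KO paclitaxel.

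The series title concerns GLI2 in the response to paclitaxel, and the response of WT cells gives its starting point. In WT cells paclitaxel raised most polyadenylated histone transcripts and inflammatory genes tested and lowered most DNA replication, mitosis and cholesterol synthesis genes. The dynein heavy chain gene DNAH3 rose from 0.0940 ± 0.0108 to 7.01 ± 0.353 CPM (SD, n = 3; log2 fold change 6.19 ± 0.20) and the histone gene H2BC21 from 0.531 to 16.1 CPM (4.90 ± 0.11). DHRS2, a short-chain dehydrogenase, rose from 4.82 to 69.3 CPM (3.84 ± 0.14). The other large rises were H2BC4 (4.31 ± 0.16), NEB (4.19 ± 0.18), which encodes the muscle thin-filament protein nebulin, ARL14 (4.06 ± 0.14), H4C8 (4.05 ± 0.12), CPNE7 (4.02 ± 0.13), H2AC6 (3.88 ± 0.08) and RELN (3.83 ± 0.19). Fatty acid synthase (FASN) fell from 1860 to 804 CPM (-1.21 ± 0.08), with its regulator SREBF1 (-1.19 ± 0.08), the laminin chain gene LAMA3 (-1.17 ± 0.04) and the histone variant gene H2AX (-1.17 ± 0.04). The remaining large falls were PINLYP (-1.44 ± 0.10), the long noncoding RNA MANCR (-1.30 ± 0.04), ACP7 (-1.20 ± 0.14), NEURL1B (-1.18 ± 0.07), PAQR4 (-1.20 ± 0.06), which shares 41.5% of its exon bases with PKMYT1, and RTEL1-TNFRSF6B (-1.70 ± 0.10), a read-through gene that shares 62.3%. Adjusted p-values of these genes were at most 3.17e-07.

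Most DNA replication and mitosis genes fell. Among 38 tested DNA replication and S-phase genes 37 fell, 0 rose and 1 did not pass, with 37 falls adjusted over the list alone and a median of -0.61 (camera adjusted p = 1.31e-19, and adjusted p = 0.124 with an estimated correlation). Examples were RRM2, a subunit of ribonucleotide reductase (-1.04 ± 0.03), and the replicative helicase subunits MCM5 (-0.95 ± 0.03) and MCM6 (-0.94 ± 0.03). Of 41 G2/M and mitosis genes 39 fell and 2 did not pass, 39 adjusted over the list alone. The median was -0.38 (adjusted p = 4.79e-13, and adjusted p = 0.234 with an estimated correlation). Examples were the spindle midzone gene PRC1 (-0.91 ± 0.20), CDCA3 (-0.83 ± 0.05) and TOP2A (-0.76 ± 0.03). Replication-dependent histone genes, whose usual transcripts end without a poly(A) tail, went the other way: 12 of 14 rose and 2 did not pass, 12 adjusted over the list alone. Their median change was 3.35 (adjusted p = 1.48e-06, and adjusted p = 0.207 with an estimated correlation). Since RNA was selected by poly(A), these values count polyadenylated histone transcripts.

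Most cholesterol biosynthesis and ER unfolded protein response genes fell. The cholesterol biosynthesis list had 21 falls of 23 and 2 that did not pass, with 1 rise and 21 falls adjusted over the list alone. The list had a median of -0.36 (adjusted p = 1.24e-07, and adjusted p = 0.319 with an estimated correlation). Examples were FDPS (-0.90 ± 0.03) and MVD (-0.79 ± 0.05). Of 21 ER unfolded protein response genes 20 fell and 1 rose, the same numbers adjusted over the list alone. The median stood at -0.42 (adjusted p = 2.84e-06, and adjusted p = 0.207 with an estimated correlation). Examples were the chaperone gene HSPA5 (-0.87 ± 0.18) and PDIA4 (-0.80 ± 0.06). Among 20 SRF and actin cytoskeleton genes 13 fell, 4 rose and 3 did not pass, likewise adjusted over the list alone (median -0.37, adjusted p = 0.00158, and adjusted p = 0.207 with an estimated correlation); ACTG1 fell by 0.58 on the log2 scale and TAGLN rose by 0.81. Cytosolic ribosomal protein genes (0 rose, 21 of 43 fell, 22 did not pass, 20 falls adjusted over the list alone; median -0.11, adjusted p = 0.00299, and adjusted p = 0.669 with an estimated correlation) turned with the scaling, to 13 rises and 5 falls (median 0.05) with library totals and 7 and 6 (median 0.03) with upper-quartile factors. Nuclear-encoded oxidative phosphorylation genes (2 rose, 19 of 33 fell, 12 did not pass, the same adjusted over the list alone; median -0.14, adjusted p = 0.00795, and adjusted p = 0.509 with an estimated correlation) likewise gave 11 rises and 10 falls (median 0.02) with library totals. The camera call of that list was lost with library totals (adjusted p = 0.311) and with upper-quartile factors (median -0.004, adjusted p = 0.192).

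Most tested NF-kB, AP-1, TGF-beta, bone metastasis and epithelial genes rose. Of 25 NF-kB and inflammatory cytokine genes 21 rose, 1 fell and 3 did not pass, the same adjusted over the list alone. The median change was 1.04 (adjusted p = 9.13e-06, and adjusted p = 0.215 with an estimated correlation). The chemokine gene CXCL1 rose by 3.32 ± 0.41 on the log2 scale, IL1B by 2.43 ± 0.39 and the NF-kB inhibitor TNFAIP3 by 2.40 ± 0.17. Among 30 AP-1 and immediate early genes 19 rose, 5 fell and 6 did not pass, with 20 rises and 5 falls adjusted over the list alone. The members had a median of 0.46 (adjusted p = 0.00155, and adjusted p = 0.215 with an estimated correlation). The largest changes were EGR2 (4.01 ± 0.21), EGR1 (3.56 ± 0.24) and FOS (2.10 ± 0.20). The TGF-beta response list had 18 rises, 5 falls and 2 that did not pass of 25, with 18 and 6 adjusted over the list alone (median 0.53, adjusted p = 0.00123, and adjusted p = 0.124 with an estimated correlation), and ID2 (2.59 ± 0.09), INHBA (1.91 ± 0.09) and SMAD7 (1.60 ± 0.07) were among them. Of 23 bone metastasis and osteolysis factors 16 rose, 2 fell and 5 did not pass, the same adjusted over the list alone. The median was 0.47 (adjusted p = 0.0023, and adjusted p = 0.207 with an estimated correlation). Here CSF2 rose by 1.91 ± 0.11 on the log2 scale and MMP1 by 2.73 ± 0.33, and TNFSF11, the osteoclast factor RANKL, went from 0 counts in 3 DMSO libraries to 54 counts, at least 19.6-fold higher against 3 counts over the group. Epithelial markers had 13 rises, 3 falls and 4 that did not pass of 20, the same adjusted over the list alone. Their median change was 0.50 (adjusted p = 0.0068, and adjusted p = 0.207 with an estimated correlation). Examples were MARVELD2 at 3.21 ± 0.20 and E-cadherin (CDH1) at 1.52 ± 0.46.

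Hedgehog genes went both ways. Of 22 tested pathway components 6 rose, 13 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.251, not called, and fry adjusted p = 2.24e-05, lower). The median of -0.14 had the opposite sign to the mean of 0.14 and turned to 0.02 with library totals. The ligand gene SHH rose by 1.26 ± 0.17 on the log2 scale, while GLI2 fell as above. Among 26 reported GLI target genes 16 rose, 4 fell and 6 did not pass, with 17 rises and 4 falls adjusted over the list alone (median 0.54, adjusted p = 0.0121, and adjusted p = 0.207 with an estimated correlation), CCND2, which encodes a D-type cyclin, rising by 2.12 ± 0.18 on the log2 scale. Of the marker lists of other cells, 6 of 6 stromal fibroblast and osteoblast genes rose, 6 adjusted over the list alone (median 1.68, adjusted p = 0.034, and adjusted p = 0.207 with an estimated correlation), a call also lost with upper-quartile factors (adjusted p = 0.0630) and library totals (0.0661). Their levels stayed low, as with PDGFRA at 1 count in DMSO and 29 in paclitaxel over the group (ratio 31.6, interval 5.24 to 1291). In addition 4 of 6 haematopoietic markers rose (adjusted p = 0.0831), 2 of 2 tested kidney and packaging cell markers rose, and 3 of 13 luminal markers rose and 5 fell (adjusted p = 0.783), the same numbers adjusted over each list alone, although luminal markers gave 5 rises and 4 falls with library totals.

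Paclitaxel changed 14660 of 21974 genes in WT cells, 7613 higher and 7047 lower. At least 2-fold changes were 3953 higher and 129 lower, against 4559 and 63 with library totals, 4467 and 65 with upper-quartile factors and 1673 and 43 with a minimum count of 50. Camera called 15 of 40 lists, 8 higher and 7 lower, and 0 with an estimated correlation. The split depended on the scaling: upper-quartile factors gave 9905 higher and 4731 lower, with all log2 fold changes shifted by a median of 0.13, and library totals gave 10352 and 4295, with a shift of 0.16. Total RNA per cell was not measured, so every change is relative to the other genes.

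In GLI2 KO cells paclitaxel lowered most DNA replication, mitosis and cholesterol synthesis genes, raised most histone and inflammatory genes, and raised 15 of 25 integrated stress response genes. DNAH3 rose by 5.97 ± 0.16 on the log2 scale, DHRS2 from 1.93 to 80.3 CPM (5.39 ± 0.16), and the immediate early transcription factors EGR1 from 29.4 to 630 CPM (4.42 ± 0.26) and EGR2 (4.97 ± 0.21). The other large rises were SPX (4.52 ± 0.15), the complement protease gene C1S (4.18 ± 0.15), CPNE7 (4.07 ± 0.12), ARL14 (3.79 ± 0.13), CHILL1 (3.42 ± 0.14) and ARRDC4 (3.37 ± 0.13). FASN fell from 3086 to 1192 CPM (-1.37 ± 0.08), and the kinetochore gene SPC24 (-1.39 ± 0.05), GINS2 (-1.35 ± 0.04), RRM2 (-1.31 ± 0.03), which shares 20.2% of its exon bases with another gene, LAMA3 (-1.23 ± 0.04), MANCR (-1.26 ± 0.04), TCF19 (-1.24 ± 0.03), WDR76 (-1.23 ± 0.04), SLCO4C1 (-1.27 ± 0.10) and PAQR4 (-1.36 ± 0.06) fell by similar amounts. Adjusted p-values of these genes were at most 4.65e-07.

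Of 25 integrated stress response genes in GLI2 KO cells 15 rose, 6 fell and 4 did not pass, the same adjusted over the list alone. The list had a median of 0.62 (camera adjusted p = 0.0122, and adjusted p = 0.648 with an estimated correlation). The transcription factor gene ATF3 (2.69 ± 0.17) rose with STC2 (2.63 ± 0.09), and the hormone gene FGF21 went from 2 to 156 counts over the group, a ratio of 77.0 (interval 20.97 to 642). All 38 DNA replication and S-phase genes fell, 38 adjusted over the list alone. The median stood at -0.85 (adjusted p = 7.34e-24, and adjusted p = 0.208 with an estimated correlation). G2/M and mitosis genes had 39 falls of 41 and 2 that did not pass, 39 adjusted over the list alone (median -0.34, adjusted p = 3.06e-11, and adjusted p = 0.36 with an estimated correlation), and cholesterol biosynthesis 22 falls of 23 and 1 that did not pass, 22 adjusted over the list alone. The sterol median change was -0.44 (adjusted p = 1.44e-09, and adjusted p = 0.36 with an estimated correlation). Histone genes rose in 11 of 14 and 3 did not pass, 11 adjusted over the list alone. The members had a median of 2.14 (adjusted p = 8.48e-05, and adjusted p = 0.332 with an estimated correlation).

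The NF-kB list in GLI2 KO cells had 20 rises of 25 and 5 that did not pass, 20 adjusted over the list alone. The median was 0.90 (adjusted p = 4.29e-06, and adjusted p = 0.332 with an estimated correlation). Examples were CXCL1 at 2.97 ± 0.36 and TNFAIP3 at 2.64 ± 0.16. TGF-beta response genes had 15 rises, 4 falls and 6 that did not pass, with 16 and 5 adjusted over the list alone. Their median change was 0.59 (adjusted p = 0.00398, and adjusted p = 0.208 with an estimated correlation). Bone metastasis factors had 16 rises, 1 fall and 6 that did not pass, with 16 and 2 adjusted over the list alone. The list had a median of 0.37 (adjusted p = 0.00433, and adjusted p = 0.318 with an estimated correlation). TNFSF11 went from 0 to 69 counts, at least 22.7-fold higher against 3 counts over the group. AP-1 genes had 16 rises, 6 falls and 8 that did not pass, with 17 and 6 adjusted over the list alone (median 0.31, adjusted p = 0.00542, and adjusted p = 0.448 with an estimated correlation), and epithelial markers 14 rises, 3 falls and 3 that did not pass, with 15 and 3 adjusted over the list alone. The median stood at 0.46 (adjusted p = 0.0107, and adjusted p = 0.318 with an estimated correlation). ER unfolded protein response genes had 15 falls, 1 rise and 5 that did not pass, with 16 falls and 1 rise adjusted over the list alone. The median change was -0.33 (adjusted p = 0.000341, and adjusted p = 0.508 with an estimated correlation). SRF and actin genes had 16 falls and 4 rises, the same adjusted over the list alone. The members had a median of -0.37 (adjusted p = 0.000596, and adjusted p = 0.318 with an estimated correlation).

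Ribosomal protein genes in GLI2 KO cells had 33 falls of 43 and 10 that did not pass (median -0.16, adjusted p = 0.000122, and adjusted p = 0.667 with an estimated correlation) and oxidative phosphorylation genes 24 falls of 33 and 9 that did not pass (median -0.17, adjusted p = 0.000122, and adjusted p = 0.619 with an estimated correlation), and with library totals the former turned to 9 rises and 4 falls (median 0.02) and the latter to 5 rises and 8 falls (median 0.00). Both counts were the same adjusted over the list alone. Heat shock genes had 9 falls, 2 rises and 4 that did not pass of 15, with 10 and 2 adjusted over the list alone (median -0.24, adjusted p = 0.0327, and adjusted p = 0.619 with an estimated correlation), a call also lost without GLI2 KO DMSO replicate 2 (adjusted p = 0.0534), without GLI2 KO paclitaxel replicate 3 (0.0503) and with upper-quartile factors (0.0820) or library totals (0.177). Stromal markers had 5 rises of 6 and 1 that did not pass, 5 adjusted over the list alone. The median was 0.95 (adjusted p = 0.0107, and adjusted p = 0.318 with an estimated correlation). Hedgehog components gave 6 rises, 9 falls and 7 that did not pass, the same adjusted over the list alone (camera adjusted p = 0.47, not called, and fry adjusted p = 2.42e-05, lower), a balance that turned to 12 rises and 4 falls with library totals, and GLI targets 15 rises, 6 falls and 5 that did not pass, the same adjusted over the list alone (adjusted p = 0.223), with CCND2 at 4.65 ± 0.27.

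Paclitaxel changed 14327 genes in GLI2 KO cells, 7250 higher and 7077 lower, with at least 2-fold changes in 3526 higher and 180 lower, against 4195 and 89 with library totals, 3969 and 110 with upper-quartile factors and 1490 and 76 with a minimum count of 50. Camera called 16 of 40 lists, 8 in each direction, and 0 with an estimated correlation. Upper-quartile factors gave 9324 higher and 4791 lower (median shift 0.12) and library totals 10398 and 3831 (median shift 0.18). The 2 responses were close across genes. Log2 fold changes in WT and GLI2 KO cells correlated at Pearson 0.871 and Spearman 0.850 over 21974 genes, which are not independent replicates. The least-squares slope of the GLI2 KO on the WT changes was 0.83. Noise in the WT changes lowers such a slope, so by itself it does not show a weaker response in GLI2 KO cells. Of 11881 genes called in both genotypes 98.7% moved the same way. Both rose for 5866 genes, against 2512 for independent lists of these sizes, and both fell for 5860, against 2270. Both sets of calls share the depth and the estimated spread of each gene, which raises such an overlap by itself.

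**Figure D3:**
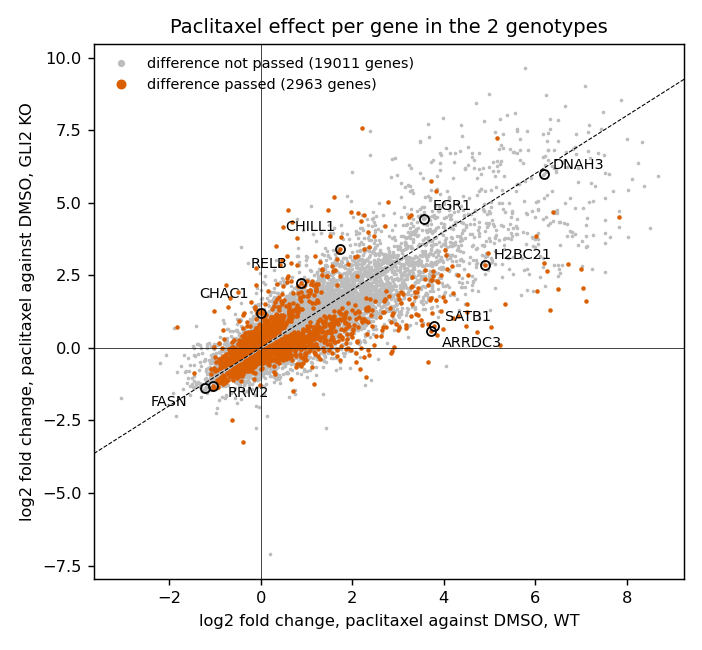
Log2 fold change with paclitaxel in WT cells (horizontal) against that in GLI2 KO cells (vertical) for 21974 genes, with the line of equal effect dashed and 2963 genes whose difference passed in orange. Named points include ARRDC3 and H2BC21 below the line and CHAC1 and RELB above it.

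The comparison of genotypes in DMSO asks what the GLI2 guide, or the derivation of the line that carries it, changed without the drug. GLI2 KO cells held more of most matrix metalloprotease, hypoxia and cholesterol synthesis transcripts tested and less of most NRF2 antioxidant transcripts. TRIM61 (chromosome 4 from 164954446 to 164977668) was nearly absent from GLI2 KO cells, with 657, 513 and 542 counts in the WT replicates and 2, 0 and 0 in the GLI2 KO replicates, a ratio of 815 (interval 225 to 6739). It shares 33.2% of its exon bases with a neighbouring gene. The long noncoding RNA UCA1 fell from 5.80 to 0.137 CPM (-5.39 ± 0.22) and GPAT2, a glycerol-3-phosphate acyltransferase, from 32.5 to 3.40 CPM (-3.26 ± 0.06). The other large falls were SLC22A31 (-3.17 ± 0.15), the granzyme B inhibitor SERPINB9 (-2.82 ± 0.11), PPP4R4 (-2.76 ± 0.12), GALNT12 (-2.75 ± 0.10), which shares 21.1% of its exon bases, the adhesion molecule L1CAM (-2.70 ± 0.10), ZNF727 (-2.69 ± 0.12) and IGFN1 (-2.64 ± 0.21). The sestrin SESN3 rose from 0.252 to 5.61 CPM (4.47 ± 0.21) and the lectin SIGLEC15 from 0.412 to 8.64 CPM (4.37 ± 0.12). RAB17 (3.72 ± 0.35), NHSL2 (3.70 ± 0.20), the interferon-inducible GTPase GBP2 (3.49 ± 0.19), PRKG1 (3.40 ± 0.13), the microtubule-associated protein MAP2 (3.31 ± 0.14), the desmosomal cadherin DSC2 (3.17 ± 0.12), SH3BGRL2 (3.16 ± 0.08) and TP73 (3.03 ± 0.11) followed. Adjusted p-values of these genes were at most 2.94e-05.

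Of 19 matrix metalloprotease and plasminogen genes 12 rose, 1 fell and 6 did not pass, the same adjusted over the list alone. Their median change was 0.34 (camera adjusted p = 0.0108, and adjusted p = 0.49 with an estimated correlation). Examples were MMP3 at 4.65 ± 0.73, MMP10 at 3.23 ± 0.63 and MMP1 at 3.14 ± 0.32. Hypoxia and glycolysis genes had 17 rises, 2 falls and 7 that did not pass of 26, with 18 and 3 adjusted over the list alone. The list had a median of 0.25 (adjusted p = 8.17e-06, and adjusted p = 0.67 with an estimated correlation). Examples were VEGFA (0.77 ± 0.06) and the glycolytic enzyme ENO1 (1.11 ± 0.04). Cholesterol biosynthesis genes had 16 rises of 23 and 7 that did not pass, 18 rises adjusted over the list alone. The median stood at 0.20 (adjusted p = 8.17e-06, and adjusted p = 0.67 with an estimated correlation). INSIG1, a brake on sterol synthesis, rose by 0.94 ± 0.07 on the log2 scale. The median was 0.17 (adjusted p = 7.06e-05) without GLI2 KO replicate 3, which stood apart. Epithelial markers had 10 rises, 1 fall and 9 that did not pass of 20, the same adjusted over the list alone. The median change was 0.23 (adjusted p = 0.0167, and adjusted p = 0.67 with an estimated correlation). Examples were the splicing regulator ESRP1 at 2.22 ± 0.15 and CLDN1 at 1.62 ± 0.09. Luminal markers had 8 rises, 3 falls and 2 that did not pass of 13, with 9 and 3 adjusted over the list alone (median 0.65, adjusted p = 0.0313, and adjusted p = 0.67 with an estimated correlation): TFF1 rose by 2.21 ± 0.24 on the log2 scale, AGR2 by 1.56 ± 0.12, and the progesterone receptor gene PGR went from 1 count to 640 over the group, a ratio of 672 (interval 120 to 26577).

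NRF2 antioxidant targets had 13 falls, 2 rises and 5 that did not pass of 20, the same adjusted over the list alone. The members had a median of -0.33 (adjusted p = 0.000877, and adjusted p = 0.67 with an estimated correlation). Examples were NQO1 (-1.16 ± 0.05) and OSGIN1 (-0.98 ± 0.10). ER unfolded protein response genes had 9 rises, 3 falls and 9 that did not pass of 21, with 10 and 3 adjusted over the list alone (median 0.13, adjusted p = 0.0476, and adjusted p = 0.908 with an estimated correlation), and the call was also lost without GLI2 KO replicate 1 (adjusted p = 0.0648), GLI2 KO replicate 2 (0.152) or WT replicate 2 (0.108). Ribosomal protein genes had 11 falls, 3 rises and 29 that did not pass of 43, the same adjusted over the list alone (median -0.08, adjusted p = 0.0159, and adjusted p = 0.908 with an estimated correlation), lost too without GLI2 KO replicate 3 (adjusted p = 0.232), without WT replicate 1 (0.170) and with fry (0.248). RPS3A fell by 0.92 ± 0.04 on the log2 scale. The Hedgehog components, with 6 rises, 6 falls and 10 that did not pass of 22 (7 and 6 adjusted over the list alone), and the reported GLI targets, with 12 rises, 6 falls and 8 that did not pass of 26 (12 and 7 adjusted over the list alone), were not called by camera (adjusted p = 0.767 and 0.342). The Hedgehog antagonist HHIP rose by 0.85 ± 0.17 on the log2 scale and CCND2 fell by 2.91. Of the genes named for this comparison, ENO1 (block median 0.89), GBP2 (0.57) and ESRP1 (0.48) lie in blocks of 50 neighbouring genes that were higher as a whole. TRIM61, RPS3A and HHIP (-0.38) and PPP4R4 (-0.18) lie in blocks that were lower.

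Between the genotypes in DMSO 9139 genes differed, 4826 higher and 4313 lower in GLI2 KO cells. At least 2-fold differences were 911 higher and 568 lower, against 551 and 348 with a minimum count of 50. Camera called 8 of 40 lists, 6 higher and 2 lower, and 0 with an estimated correlation. The balance over all differing genes turned with upper-quartile factors (4336 higher and 4877 lower) and library totals (4267 and 4939). Each genotype is represented by a line whose clonal history is not given in the sources used here, so a difference between the genotypes includes any other difference between the lines. The libraries were also numbered by genotype, 1 to 6 for WT and 7 to 12 for GLI2 KO.

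**Figure D4:**
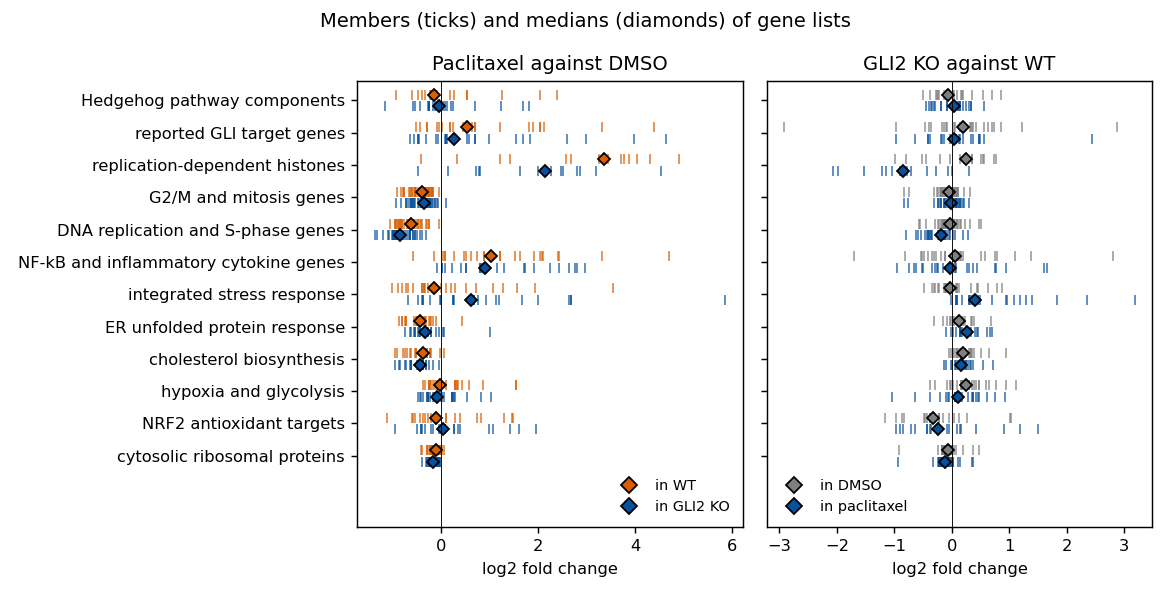
Log2 fold changes of the tested members (ticks) and their median (diamonds) for 12 gene lists, with paclitaxel against DMSO by genotype (left) and GLI2 KO against WT by treatment (right). Medians of the integrated stress response were -0.13 in WT (0.02 with library totals) and 0.62 in GLI2 KO cells with paclitaxel, and those of histone genes 3.35 and 2.14.

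The same comparison under paclitaxel asks how the genotypes differed once treated. GLI2 KO cells then held more of most integrated stress response and ER unfolded protein response transcripts tested and less of most DNA replication and histone transcripts. TRIM61 again gave 656, 737 and 755 counts in WT replicates against 0, 1 and 2 in GLI2 KO replicates, a ratio of 753 (interval 257 to 3654), and UCA1 fell from 22.6 to 0.292 CPM (-6.25 ± 0.16). GPAT2 (-2.88 ± 0.06), SERPINB9 (-2.66 ± 0.11), the alpha-arrestin ARRDC3 (-2.57 ± 0.12), IGFN1 (-2.30 ± 0.17), RCSD1 (-2.25 ± 0.11), ZNF727 (-2.15 ± 0.11), the aldehyde dehydrogenase ALDH3A1 (-2.10 ± 0.29) and H2BC21 (-2.06 ± 0.08) were also lower. SIGLEC15 (3.67 ± 0.11), PWWP3B (3.55 ± 0.10), the chromatin organiser SATB1 (3.43 ± 0.13), NNMT (3.08 ± 0.10), SESN3 (3.08 ± 0.16), PRKG1 (2.86 ± 0.12), MAL2 (2.66 ± 0.12), SH3BGRL2 (2.66 ± 0.08), PTPRQ (2.52 ± 0.11) and RAB17 (2.51 ± 0.26) were higher. Adjusted p-values of these genes were at most 0.000346.

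Of 25 integrated stress response genes 18 rose and 7 did not pass, 19 rises adjusted over the list alone. The median was 0.41 (camera adjusted p = 2.32e-08, and adjusted p = 0.194 with an estimated correlation). Examples were CHAC1, which degrades glutathione, at 1.84 ± 0.15 and cystathionine gamma-lyase (CTH) at 1.39 ± 0.12. ER unfolded protein response genes had 16 rises, 1 fall and 4 that did not pass of 21, with 18 and 1 adjusted over the list alone. Their median change was 0.27 (adjusted p = 5.98e-05, and adjusted p = 0.458 with an estimated correlation). Examples were HYOU1 (0.69 ± 0.05) and XBP1 (0.61 ± 0.06). DNA replication and S-phase genes had 30 falls, 2 rises and 6 that did not pass of 38, with 31 and 3 adjusted over the list alone. The list had a median of -0.20 (adjusted p = 6.68e-09, and adjusted p = 0.194 with an estimated correlation). MCM6 (-0.62 ± 0.03), PCNA (-0.53 ± 0.03) and POLE2 (-0.80 ± 0.04) were among the falls. Histone genes had 9 falls of 14 and 5 that did not pass, 9 adjusted over the list alone. The median stood at -0.84 (adjusted p = 1.99e-05, and adjusted p = 0.403 with an estimated correlation). Cholesterol genes had 15 rises, 1 fall and 7 that did not pass, with 16 and 2 adjusted over the list alone. The median change was 0.16 (adjusted p = 0.000272, and adjusted p = 0.573 with an estimated correlation).

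Under paclitaxel epithelial markers had 10 rises, 3 falls and 7 that did not pass of 20, with 11 and 3 adjusted over the list alone (median 0.26, adjusted p = 0.0292, and adjusted p = 0.291 with an estimated correlation), and luminal markers 10 rises and 3 falls, the same adjusted over the list alone. The members had a median of 0.60 (adjusted p = 0.0232, and adjusted p = 0.229 with an estimated correlation). Examples were ESRP1 at 2.32 ± 0.14 and PGR at 243 counts against 2, a ratio of 116 (interval 31.6 to 959). Hypoxia genes had 13 rises, 5 falls and 8 that did not pass of 26, with 14 and 5 adjusted over the list alone (median 0.11, adjusted p = 0.0227, and adjusted p = 0.728 with an estimated correlation), a call also lost without GLI2 KO paclitaxel replicate 1 (adjusted p = 0.0537). Ribosomal protein genes had 23 falls, 3 rises and 17 that did not pass of 43, with 25 and 4 adjusted over the list alone (median -0.12, adjusted p = 0.00102, and adjusted p = 0.876 with an estimated correlation), a call also lost with fry (adjusted p = 0.0694). Hedgehog components had 6 rises, 7 falls and 9 that did not pass of 22 (7 and 7 adjusted over the list alone, camera adjusted p = 1) and GLI targets 5 rises, 8 falls and 13 that did not pass of 26 (5 and 8 adjusted over the list alone, adjusted p = 0.949). Of the genes named for this comparison, ESRP1 (block median 0.46), HYOU1 (0.44), NNMT (0.42), ALDH3A1 (0.24) and MAL2 (0.17) lie in blocks of neighbouring genes that were higher as a whole, and POLE2 (-0.43), TRIM61 (-0.36), PCNA (-0.34) and MCM6 (-0.26) in blocks that were lower.

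Under paclitaxel 10028 genes differed between genotypes, 5152 higher and 4876 lower in GLI2 KO cells. At least 2-fold differences were 766 higher and 632 lower, against 404 and 311 with a minimum count of 50. Camera called 9 of 40 lists, 6 higher and 3 lower, and 0 with an estimated correlation. The balance over all differing genes turned with upper-quartile factors (4427 higher and 5706 lower) and library totals (5012 and 5016). It also turned with no low-count filter (4964 and 5101) and a minimum count of 50 (4560 and 4734). Genotype effects in DMSO and in paclitaxel correlated at Pearson 0.683 and Spearman 0.583 across genes, and at a Pearson value of 0.829 among genes with a minimum count of 50. The slope over all genes was 0.54. Noise lowers this slope too, so by itself it does not show a smaller genotype effect under paclitaxel. Of 6489 genes called under both treatments 96.5% differed the same way. Both were higher for 3366 genes, against 1132 for independent lists, and both lower for 2899, against 957. Here too the shared depth and estimated spread of each gene raise the overlap by themselves.

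Whether GLI2 KO cells responded differently to paclitaxel was tested by the difference of the 2 responses. Below, higher and lower compare the log2 fold change with paclitaxel in GLI2 KO cells with that in WT cells, so a lower value is a smaller rise or a larger fall. It was higher for 14 of 25 integrated stress response genes. The rise of histone genes was smaller for 7 of 14, and the fall of DNA replication genes was larger for 27 of 38. Of 25 integrated stress response genes 14 were higher and 11 did not pass, 17 higher adjusted over the list alone. The median was 0.52 (camera adjusted p = 1.4e-17, and adjusted p = 0.24 with an estimated correlation). CHAC1 stayed at 5.35 ± 0.357 and 5.39 ± 0.448 CPM in WT cells and went from 8.34 ± 2.06 to 19.2 ± 0.398 CPM (SD, n = 3) in GLI2 KO cells, a difference of 1.203 ± 0.22 (adjusted p = 0.00521). Asparagine synthetase (ASNS) differed by 1.53 ± 0.22, CTH by 1.07 ± 0.17, STC2 by 1.06 ± 0.14 and the glycine transporter gene SLC6A9, which is not in that list, by 1.07 ± 0.13.

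Histone genes were lower, a smaller rise, in 7 of 14 and 7 did not pass, 8 adjusted over the list alone. Their median was -1.28 (adjusted p = 1.43e-06, and adjusted p = 0.285 with an estimated correlation). H2BC21 reached 16.1 CPM in WT and 3.85 CPM in GLI2 KO cells (difference -2.04 ± 0.20), and H2BC5 (-2.07 ± 0.13), H2BC12 (-1.96 ± 0.17), H2BC4 (-1.78 ± 0.28) and H2AC6 (-1.60 ± 0.12) differed likewise. DNA replication and S-phase genes were lower, a larger fall, in 27 of 38 and 11 did not pass, 27 adjusted over the list alone. The list had a median of -0.20 (adjusted p = 6.26e-17, and adjusted p = 0.24 with an estimated correlation). Examples were CCNE2 (-0.50 ± 0.06) and GINS2 (-0.43 ± 0.05). ARRDC3 went from 18.4 to 245 CPM in WT and from 27.6 to 41.3 CPM in GLI2 KO cells (-3.15 ± 0.17, adjusted p = 1.57e-05). The hyaluronan synthase gene HAS2 went from 4.19 to 6.62 CPM in WT and from 17.8 to 8.39 CPM in GLI2 KO cells (-1.75 ± 0.11).

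Collagen and matrix genes were lower in 8 of 24, higher in 1 and 15 did not pass, with 12 and 1 adjusted over the list alone. The median stood at -0.25 (adjusted p = 2.41e-05, and adjusted p = 0.358 with an estimated correlation). An example was the collagen gene COL4A1 at -0.34 ± 0.06. Metalloprotease and plasminogen genes were lower in 7 of 19 and 12 did not pass, 7 adjusted over the list alone. The median change was -0.21 (adjusted p = 0.00454, and adjusted p = 0.24 with an estimated correlation). An example was ADAMTS1 at -1.40 ± 0.29. Hypoxia genes were lower in 6 of 26 and 20 did not pass, 8 adjusted over the list alone. The members had a median of -0.10 (adjusted p = 0.00017, and adjusted p = 0.461 with an estimated correlation). An example was adrenomedullin (ADM) at -0.995 ± 0.08. Lysosome and autophagy genes were lower in 6 of 22 and 16 did not pass, with 11 lower and 1 higher adjusted over the list alone. The median was -0.11 (adjusted p = 0.0106, and adjusted p = 0.461 with an estimated correlation). An example was GPNMB at -1.03 ± 0.12. Reported GLI targets were lower in 4 of 26, higher in 1 and 21 did not pass, the same adjusted over the list alone. Their median was -0.16 (adjusted p = 0.0116, and adjusted p = 0.24 with an estimated correlation). BMP4 (-0.53 ± 0.06), CCN1 (-0.48 ± 0.06) and SOX9 (-0.47 ± 0.06) were lower and CCND2 was higher (2.53 ± 0.38). ER unfolded protein response genes were higher in 3 of 21, lower in 1 and 17 did not pass, the same adjusted over the list alone (median 0.07, adjusted p = 0.0116, and adjusted p = 0.685 with an estimated correlation), a call lost without GLI2 KO DMSO replicate 3 (adjusted p = 0.144), GLI2 KO paclitaxel replicate 1 (0.0668) or WT DMSO replicate 1 (0.0701) and with fry (0.334). Hedgehog components gave 1 higher, 1 lower and 20 that did not pass of 22, the same adjusted over the list alone (adjusted p = 0.895).

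The response differed for 2963 genes, 1441 higher and 1522 lower in GLI2 KO cells, and 9 of 40 lists were called, 2 higher and 7 lower, and 0 with an estimated correlation. The balance turned with library totals (1770 higher and 1249 lower), RLE factors (1551 and 1356) and DESeq2 (1744 and 1413), and not with upper-quartile factors (1298 and 1707). Among the 2963 genes 1025 responded in the same direction and more strongly in GLI2 KO cells, 1113 in the same direction and less strongly, and 825 in opposite directions, of which 155 passed in both genotypes. Without GLI2 KO paclitaxel replicate 2 the count was 2128, and without GLI2 KO DMSO replicate 3 it was 3443.

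**Figure D5:**
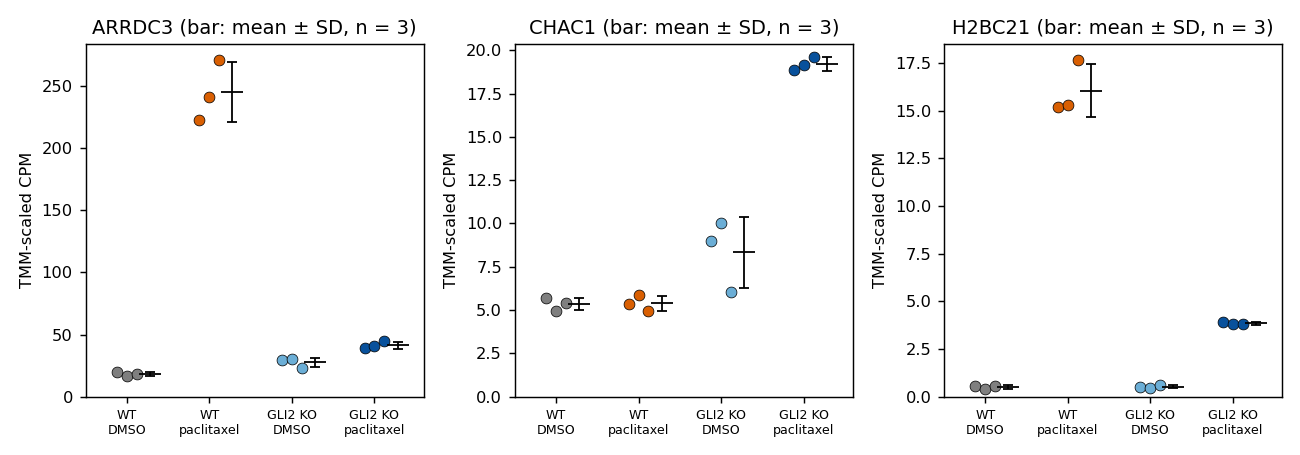
TMM-scaled CPM of ARRDC3, CHAC1 and H2BC21 in each of the 12 samples, with mean and SD (n = 3) per group. ARRDC3 reached 245 CPM in WT and 41.3 CPM in GLI2 KO cells with paclitaxel, and CHAC1 5.39 and 19.2 CPM.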

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

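The tests of library order, of the neighbours of GLI2 and of the 1479 genes by position, and both tests of the stress response, were chosen only after the results were seen. The response to paclitaxel differed between WT and GLI2 KO cells for 2963 genes by a test of the difference itself, and each result below is there for that reason. Of 40 splits drawn from 200 possible ones, 1 gave as many genes, the real one, and the highest other gave 2503. Most splits other than the real one put both genotypes in a group, so the genotype effect widened the spread there. The splits therefore cannot show that the 2963 genes exceed chance. Higher in GLI2 KO cells were CHILL1 (1.69), ALOXE3 (1.62), DHRS2 (1.55), RELB (1.363), SPX (1.27), L1CAM (1.26), CHAC1 (1.203), ABCA10 (1.195), CTH (1.07) and SLC6A9 (1.07). Lower were ARRDC3 (-3.15), SATB1 (-3.06), CAPN8 (-2.49), H2BC5 (-2.07), H2BC21 (-2.04), H2BC12 (-1.96), H2BC4 (-1.78), HAS2 (-1.75), H2AC6 (-1.60) and DGKI (-1.50). SPX did not pass without WT DMSO replicate 1 (1.07, adjusted p = 0.0573). CAPN8, a calpain gene, had an adjusted p of 0.0488 and did not pass with library totals (0.0522), with no low-count filter (0.0555) or without any of 9 of the 12 libraries, while without GLI2 KO DMSO replicate 3 it was at -1.78 (adjusted p = 9.06e-07). SATB1 rested on low levels in WT cells (0.0309 CPM in DMSO and 0.474 in paclitaxel). List medians called at the preset correlation, all 9 of them lost with an estimated correlation (adjusted p from 0.24 to 0.685), were those of the integrated stress response (0.52) and the ER unfolded protein response (0.074, lost too with fry and without any of 3 single libraries), which were higher, and of histones (-1.28), collagens and matrix (-0.25), metalloproteases (-0.21), DNA replication and S-phase (-0.20), GLI targets (-0.16), lysosome and autophagy (-0.11) and hypoxia (-0.10), which were lower.

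Paclitaxel raised far more genes at least 2-fold than it lowered, 3953 against 129 in WT cells. An even background such as genomic DNA would add the same amount per kb to every gene. The amount added spread by a factor of 37.0 from the 10th to the 90th percentile, which argues against it as the whole cause. A part due to background was not excluded. In 8 tested olfactory receptor genes the median amount added was 0.0272 CPM per kb, near the 10th percentile of the raised genes (0.0262). The lowest ratio of raised to lowered genes over 3 scalings was 30.6. RLE factors left the log2 fold changes almost in place (median shift -0.0005). Upper-quartile factors and library totals moved them up (0.13 and 0.16). None of these scalings could lower the ratio by much, so a part due to scaling cannot be told apart. A part due to the counting floor cannot be told apart, because the ratio was 5.62 among genes at a mean of 5 CPM or more (163 against 29) and 37.9 below it, where a fall is harder to see, and a response of the cells to the drug stays open and was not tested separately. For the genes changed by paclitaxel in WT cells and in GLI2 KO cells, 1 of 10 splits each gave as many, the real ones. These gave 14660 and 14327 genes and the highest other 0, and 10 splits are too few for a share under 0.05. Every other split mixed the treatments within its groups, which widened the spread there. The splits therefore cannot show that these genes exceed chance.

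In DMSO 9139 genes differed between GLI2 KO and WT cells although the GLI2 transcript differed by 14.6% in DMSO. Regional differences between the lines, as copy-number changes would make, are consistent with part of it: the SD of medians over windows of 50 neighbouring genes was 4.58 times that of shuffled positions, against 1.65 times for paclitaxel in WT cells. For genes changed at least 2-fold, differences shared by most of the 50 nearest genes were not the whole cause. Smaller differences, most of the 9139, were not tested in this way. Of 170 genes with a mean of 5 CPM or more that changed at least 2-fold, 132 (77.6%) stayed past 2-fold after the median of the 50 nearest genes was taken off. So did 1258 of 1380 with a position among the 1479 changed at any level. A gain or loss of only a few neighbouring genes would hardly move that median, so it was not excluded. In DMSO the lower GLI2 transcript cannot be told apart from its region, as GLI2 lay -0.076 from the median of its 50 nearest genes (-0.950 standard errors, 19 of 50 at or below it), whereas in paclitaxel it lay -0.33 from that median (-3.62 standard errors, 4 of 50 at or below it), further than these neighbours, though the fixed window of 50 genes that holds it had a median of -0.26. Library preparation in genotype order cannot be told apart either, as 0 GLI2 KO libraries were numbered below a WT library. An effect of losing GLI2 stays open. For 9139 genes in DMSO and 10028 in paclitaxel 1 of 10 splits each gave as many, the real ones (highest other 0). So few splits cannot give a share under 0.05. Every other split mixed the genotypes within its groups, which widened the spread, so the splits cannot show that these genes exceed chance.

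With paclitaxel 15 of 25 integrated stress response genes rose and 6 fell in GLI2 KO cells, and 7 rose and 13 fell in WT cells (8 and 9 with library totals). The GLI2 KO DMSO library that stood apart was not the cause, since without it the median difference was 0.51 (adjusted p = 8.08e-17 at the preset correlation). With all libraries the list was not called with an estimated correlation (adjusted p = 0.24), so the case rests on the 14 members that passed and on the preset correlation. The list as a whole started at nearly the same level in both genotypes, with a median difference from WT of -0.032 in DMSO. The 14 members that passed were not examined apart, so a lower starting level of some of them was not excluded. With libraries numbered by genotype and the clonal history not given, a difference between the lines other than GLI2, or in preparation, stays open beside an effect of GLI2.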

How the results depend on the processing

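The alternatives below were chosen before the data were examined. No named gene turned to a call in the opposite direction, and every total of changed genes stayed within 1.5 times its reported value under each of them. Some numbers of genes changed at least 2-fold did not. Paclitaxel lowered 63 in WT cells with library totals against 129 reported. Between genotypes in DMSO 551 were higher with a minimum count of 50 against 911 reported. Balances did turn with the scaling. With library totals the medians of ribosomal protein genes turned to 0.05 in WT and 0.02 in GLI2 KO cells with paclitaxel, and those of oxidative phosphorylation genes to 0.02 and 0.00, and with upper-quartile factors that of ribosomal protein genes in WT cells turned to 0.03, each with its call lost; the difference of effects went from 1441 higher and 1522 lower to 1770 and 1249 with library totals. Leaving out each library gave 13895 to 14183 genes for paclitaxel in WT cells, 13507 to 14315 in GLI2 KO cells, 8070 to 8909 between genotypes in DMSO, 8837 to 9318 in paclitaxel and 2128 to 3443 for the difference of effects. The lower GLI2 transcript in GLI2 KO cells in DMSO ranged from -0.30 to -0.15 and did not pass without 3 of the libraries, GLI2 KO DMSO replicates 1 (-0.23, adjusted p = 0.0577) and 2 (-0.15, 0.183) and WT DMSO replicate 2 (-0.19, 0.110); the cause was not tested. With a minimum count of 50 the correlation of the paclitaxel effects rose to 0.910 and that of the genotype effects to 0.829, where fewer and better-counted genes were tested. Without single libraries they ran from 0.841 to 0.860 and from 0.619 to 0.657. Those fits had fewer samples and also more genes (22462 to 22732 against 21974), and the 2 changes cannot be told apart. Among named genes 11124 values kept their direction and side of the threshold and 463 became weaker, 381 of them without a library. Among list tests 2241 stayed, 118 became stronger, 69 of them with fry, and 81 weaker, 57 of the latter with an estimated correlation. G2/M genes in DMSO became called with RLE factors (adjusted p = 0.0408), upper-quartile factors (0.0163) and library totals (0.0161). The share of higher genes moved to 46.4% between genotypes in DMSO with library totals and to 43.7% in paclitaxel with upper-quartile factors (49.98% with library totals). Depth limits what lies under 3 counts. Among genes with a mean of at least 50 counts, the test recovered 36 of 50 simulated 1.2-fold changes for paclitaxel in WT cells. For the difference of effects it recovered 18 of 50. Those simulations held few and balanced changes, unlike the real response to paclitaxel.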

Other observations

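The treatment of genes with 3 counts or fewer in a group was chosen after their counts were seen. The list of drug efflux and taxane handling held the transporter gene ABCB1, whose product exports paclitaxel. It went from 2 to 66 counts over the group in WT cells, a ratio of 36.0 (interval 9.57 to 303). The GLI2 KO replicates held 0, 1 and 3 counts in DMSO and 162, 163 and 191 in paclitaxel. The fitted rise there, 6.70 ± 0.36 on the log2 scale, starts near the floor, so its size is uncertain. Under the drug ABCB1 was 2.89 ± 0.22 higher on the log2 scale in GLI2 KO than in WT cells (edgeR adjusted p = 5.07e-11). The difference of effects did not pass (adjusted p = 0.442). Of the 16 genes in that list 8 rose and 6 fell in WT cells (adjusted p = 0.557) and 6 rose and 5 fell in GLI2 KO cells. Of 15 tubulin genes 8 rose and 4 fell in WT cells (adjusted p = 0.486), with TUBB2A at 1.25 ± 0.05 and TUBB3, linked to taxane resistance, at 1.23 ± 0.13. Microtubule-binding genes split 7 up and 11 down of 24 (adjusted p = 0.521), which library totals turned to 12 and 7; MAP1A rose by 1.23 ± 0.07 on the log2 scale. Among 27 p53 targets 12 rose and 11 fell (adjusted p = 0.735), with the stress cytokine gene GDF15 at 3.31 ± 0.08 and GADD45A at 1.12 ± 0.11. Pro-apoptotic BCL2-family genes split 8 and 8 of 21 (adjusted p = 0.831; 11 and 5 with library totals), with HRK at 2.63 ± 0.45, and pro-survival genes 3 and 5 of 10 (adjusted p = 0.623; 3 and 3 with library totals), with BIRC3 at 0.89 ± 0.10. Senescence genes gave 7 rises and 6 falls of 15 (adjusted p = 0.623), with the cytokine gene IL6 at 1.53 ± 0.16.

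Other lists that camera did not call for paclitaxel in WT cells were as follows, as rises and falls. All list p-values in this part are from camera, which compares a list with the other genes, and fry, which does not, called 69 of the list tests that camera did not call over the 5 comparisons. Notch genes gave 7 and 2 of 16 (adjusted p = 0.177), with the effector HEY1 at 1.79 ± 0.11, and WNT genes 7 and 3 of 14 (adjusted p = 0.346), with the receptor LGR5 at 1.53 ± 0.18. YAP targets gave 6 and 10 of 25 (adjusted p = 0.456; 13 and 8 with library totals), stem cell genes 7 and 2 of 12 (adjusted p = 0.104), and mesenchymal genes 9 and 7 of 20 (adjusted p = 0.831), with the repressor SNAI1 at 1.90 ± 0.09. Interferon-stimulated genes gave 12 and 14 of 35 (adjusted p = 0.623; 13 and 10 with library totals), MHC genes 6 and 3 of 15 (adjusted p = 0.553), and metalloproteases 12 and 4 of 19 (adjusted p = 0.0524). Collagens gave 10 and 7 of 24 (adjusted p = 0.623), lysosome genes 9 and 8 of 22 (adjusted p = 0.521), with GPNMB at 2.71 ± 0.09, and mitochondrial genes 5 and 1 of 15 (adjusted p = 0.37). NRF2 targets gave 7 and 9 of 20 (adjusted p = 0.521; 8 and 8 with library totals), hypoxia genes 10 and 10 of 26 (adjusted p = 0.831; 15 and 4 with library totals), with adrenomedullin (ADM) at 1.54 ± 0.05, and heat shock genes 2 and 7 of 15 (adjusted p = 0.11; 4 and 1 with library totals). The integrated stress response gave 7 and 13 of 25 (adjusted p = 0.456; 8 and 9 with library totals), with ATF3 at 1.94 ± 0.16. In WT cells the counts of this part were the same adjusted over the list alone, except for p53 targets (12 and 12), WNT (9 and 3), mesenchymal (10 and 7), MHC (6 and 2) and mitochondrial genes (4 and 1).

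Blocks of neighbouring genes differed between the genotypes. On chromosome 1 from 6590724 to 15786594 the median of 50 genes was 0.89 higher in GLI2 KO cells in DMSO and 0.79 higher in paclitaxel, and on chromosome 2 from 171434217 to 187565760 it was -0.53 in DMSO. Window medians in DMSO and paclitaxel correlated at 0.971 over 206 windows.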
